A study of Homo sapiens with 5 samples.

How the data were processed

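Gene expression was measured by sequencing in 5 libraries of HL60 cells, an established human promyelocytic leukaemia line. Groups were taken from the treatment labels and titles: 1 untransduced library, 2 libraries of cells carrying the SCR control lentivector and 2 of cells carrying the ZIP lentivector, which encodes a hairpin antisense to miR-378a-3p. The labels describe the control vector both as scramble and as empty, and which of these it was is not settled here. Per the labels, transduction used a multiplicity of infection of 20 with 8 µg/mL polybrene, and selection used 2 µg/mL puromycin from day 3 to day 8. Per the labels, total RNA was extracted with a mirVana kit, libraries were made with a TruSeq Small RNA kit and sequenced on a HiSeq 2500. The labels also name qPCR of the microRNA and of the vector, whose values were not used here.

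The deposited table holds raw counts per gene, without normalization by the authors, for 51055 Ensembl gene IDs in 5 columns. That the values are counts was read from the values themselves, which are whole numbers with different totals per library. The submitters' processing notes name Bowtie2 and featureCounts. The series' design text instead names CASAVA 1.8.2, TopHat 2 for alignment, Cufflinks and HTSeq for quantification, and Cuffdiff and MultiRankSeq (DEGseq, edgeR and baySeq) for testing. Which of these made the deposited counts, the genome build, the annotation release and whether counting used strand are not given in the sources used here. Overlapping and antisense genes, and genes with near-identical copies or pseudogenes, are therefore uncertain. Every column was matched to its library by the description label, 0 columns belonged to other samples and 0 entries named no gene.

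Gene IDs were matched to GENCODE release 29 (GRCh38): 44305 had a symbol there and 6750 did not, and these stayed in the tests but were not named. Coordinates are from that annotation. Library totals were 25064771 counts (untransduced), 24539092 and 24978022 (SCR), and 30925067 and 24406580 (ZIP), and 22066 to 23766 genes had a count. A group without a count was set to a floor of 3 counts over the group, and fold changes against it are given as lower bounds that leave out the counting error of the other group. Ratios of named genes with 1 to 3 counts in a group have an exact (Clopper-Pearson) 95% interval. Replicates differed by little more than counting noise: the mean chi-square per gene was 2.65 between the SCR libraries and 1.88 between the ZIP libraries, above the value of 1 that counting noise alone gives, against 88.1 to 151 between libraries of different groups. They were kept as separate replicates, and whether they are separate cultures is not given in the sources used here.

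Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), scaled by TMM (factors 0.956, 1.03, 1.03, 0.990 and 0.991) and tested with the edgeR quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05. ZIP against SCR used those 4 libraries. SCR and ZIP against untransduced used all 5, so that the single untransduced library was assumed to vary like the others. Each fit had 2 residual degrees of freedom. CPM values used the TMM-scaled library size. Fold changes are ZIP over SCR, SCR over untransduced and ZIP over untransduced.

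Gene lists were tested with camera (preset correlation 0.01) on voom log CPM (offset 0.5), adjusted over the lists with at least 5 measured genes, and again with an estimated correlation and with fry. The 36 lists covered miR-378 loci and reported targets; primary granule and secondary and tertiary granule proteins; markers of monocytes, maturing neutrophils, stem cells, erythroid cells, megakaryocytes, T and NK cells, B cells, and epithelial cells and fibroblasts; NADPH oxidase, interferon, NF-kB and immediate early genes. They also covered DNA replication, mitosis, cell cycle inhibitors, histones, apoptosis, ATF4 and the unfolded protein response, ribosomal proteins, MYC targets, nuclear and mitochondrial oxidative phosphorylation, glycolysis, fatty acid oxidation and cholesterol biosynthesis. The last were the 5q region, genes mutated in MDS, myeloid transcription factors, microRNA biogenesis, myeloid microRNA loci, heat shock and reference genes. Some genes are in more than 1 list. The lists, groups, tests of SCR and ZIP, other settings to be tried and the rule for naming genes were fixed before the data were examined. The list test of ZIP against untransduced was added after.

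Genes were named by rule in each comparison: MIR378A and its host gene PPARGC1B; the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, a mean of at least 1 CPM in a group, non-overlapping groups and an official symbol; and, of each list that passed or had a member that passed, up to 4 members of smallest p. The text does not name all of these: some whose call was lost under another setting are left out, and some genes are not reported here. The 6 primary granule genes of the mixed-cell test in the closing section were chosen after fold changes of some of them had been seen.

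Sites for miR-378a-3p (AGTCCAG, the complement of bases 2 to 8 of the microRNA) were searched in the longest annotated 3' UTR of 19141 genes. The difference in mean log2 fold change was tested by 100000 permutations of genes, two-tailed, and by 20000 permutations within bins of 3' UTR length and expression, with 200 shuffled control words of the same bases. Chromosome medians of centred log2 fold changes were tested by 10000 permutations of genes over chromosomes, and running medians over 51 neighbouring genes against 1000 random gene orders. Overlap between the comparisons against the untransduced library was set beside 20 simulations of unchanged groups.

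Alternatives were DESeq2 1.42.0, the edgeR exact test, RLE factors, library totals, no filter, a filter at a mean of 50 counts, leaving out each SCR and ZIP library, a replicate block, all 5 libraries, protein-coding genes only, and the untransduced library in place of SCR. Library totals and the last of these were chosen after the data were seen. The tests were run on simulated counts, and for the gene test 193 or 194 changed genes passed the filter. For ZIP against SCR (14366 genes) it recovered 42.6% of 1.2-fold, 73.5% of 1.5-fold, 88.0% of 2-fold and 97.9% of 4-fold changes, with 12 of 14172 unchanged genes called. For SCR against untransduced (15147 genes) these were 30.6%, 58.7%, 77.6% and 89.8%, with 14 of 14954. For ZIP against untransduced (15122 genes) they were 32.7%, 58.3%, 79.2% and 95.8%, with 18 of 14929. Far fewer genes were changed in the simulations than were called in the data, so the p-value cutoff after adjustment was stricter there. The simulated spread was that of these libraries, so the rates do not cover variation between separate cultures. In separate simulations camera passed 0 lists on unchanged counts, and it ranked a list raised 1.5-fold at 1. The simulated genes were drawn independently of each other, so this does not show whether the preset correlation holds in the data. Shifting 1 simulated chromosome made 3 chromosomes pass in ZIP against SCR. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 made the joins and plots.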

Results

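HL60, a human promyelocytic leukaemia line that grows as immature granulocyte precursors, was profiled by sequencing in 5 libraries. The libraries formed 3 groups: untransduced cells (n = 1), cells carrying a control lentivector named SCR (n = 2) and cells carrying an antisense lentivector against miR-378a-3p named ZIP (n = 2). The labels call the control vector both scramble and empty, and the name SCR is kept here. Both vectors were given at a multiplicity of infection of 20, and the transduced cells were selected with 2 µg/mL puromycin from day 3 to day 8. The series title ties knockdown of this microRNA to myelodysplastic syndrome (MDS). The deposited table held gene counts for 51055 genes, with 25064771 counts in the untransduced library, 24539092 and 24978022 in SCR 1 and SCR 2, and 30925067 and 24406580 in ZIP 1 and ZIP 2.

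The kit named in the labels is a small RNA kit, but protein-coding genes held 96.9% ± 0.197 (SD, n = 5) of the counts. Annotated microRNA loci together held 244 counts in the untransduced library, 181 and 172 in the SCR libraries, and 372 and 299 in the ZIP libraries. The values below therefore describe mRNA. At these depths 3 counts, the floor used for genes without a count, equalled 0.0980 to 0.125 CPM (counts scaled to library size) per library. Intervals and floors cover counting error only.

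The targeted microRNA was reported first. MIR378A (ENSG00000199047), on the plus strand of chromosome 5 from 149732825 to 149732890 in GRCh38, had 0 counts in the untransduced library, in both SCR libraries and in ZIP 1, and 2 counts in ZIP 2. All of these lie under the floor of 3 counts. A count at a microRNA locus also need not measure the mature microRNA, which the vector targets. Knockdown could therefore not be assessed from this locus at any depth, and the labels of the libraries could not be checked by it. The locus lies in intron 1 of the 4 PPARGC1B transcripts that span it, out of 7 annotated. Of the 11 loci of the miR-378 family list, only MIR378A was found by symbol among the genes counted, and it did not pass the expression filter. PPARGC1B (ENSG00000155846, chromosome 5, 149730298 to 149855022), which encodes a coactivator of mitochondrial and fatty acid genes, had 40.5 CPM in the untransduced library, 48.7 and 51.2 in SCR, and 67.6 and 67.7 in ZIP. Its log2 fold change was 0.44 ± 0.04 (SE) in ZIP against SCR, with an adjusted p of 6.5e-09 (edgeR quasi-likelihood test, Benjamini-Hochberg). It was 0.30 ± 0.06 in SCR against untransduced and 0.74 ± 0.05 in ZIP against untransduced.

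The first comparison set the ZIP cells beside the SCR cells. All 27 measured interferon genes and all 22 cholesterol biosynthesis genes were lower in ZIP (camera adjusted p = 1.8e-13 and 2.5e-17, and adjusted p = 0.209 for each with an estimated correlation). Of 15 primary granule genes 13 were higher, as were all 13 mitochondrially encoded mRNAs (camera adjusted p = 3.8e-07 and 5.0e-12, and adjusted p = 0.301 for each with an estimated correlation). FADS2, a fatty acid desaturase, stood at 271 and 262 CPM in SCR and at 1.27 and 0.662 CPM in ZIP, a log2 fold change of -8.05 ± 0.19 (SE, n = 2 and 2). The granule protease PRTN3 went the other way, from 821 and 834 CPM in SCR to 3286 and 3184 in ZIP. The untransduced library held 13.1 CPM of FADS2 and 3197 CPM of PRTN3, in each case nearer to ZIP than to SCR.

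**Figure D1:**
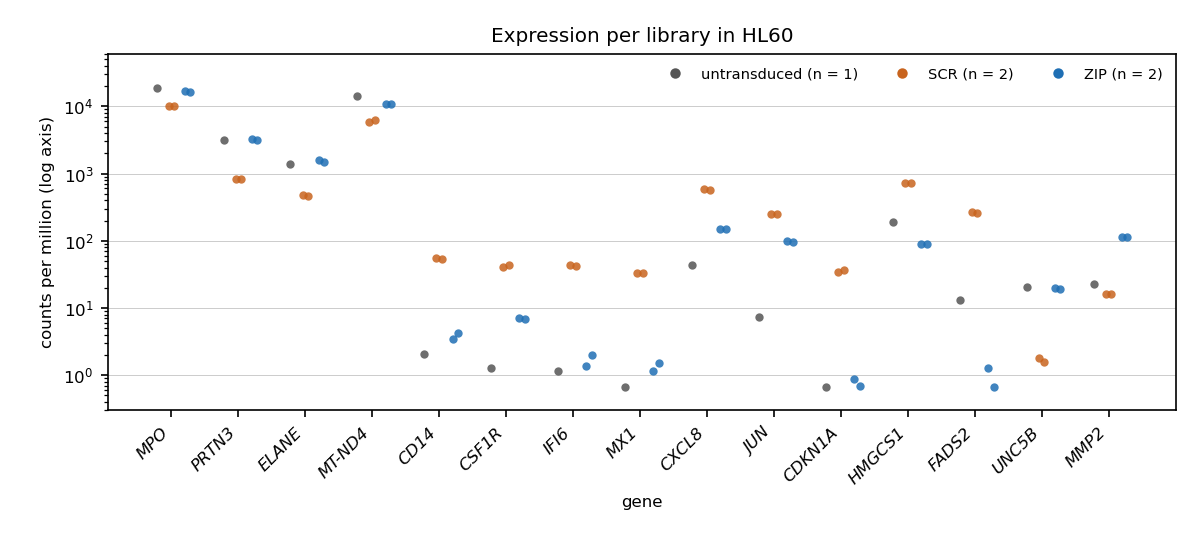
CPM (log axis) of 15 genes in each of the 5 libraries, each point a library: untransduced (n = 1), SCR (n = 2) and ZIP (n = 2). MPO, PRTN3, ELANE, MT-ND4 and UNC5B were lowest in SCR, while CD14, CSF1R, IFI6, MX1, CXCL8, JUN, CDKN1A, HMGCS1 and FADS2 were highest in SCR, and MMP2 was highest in ZIP, at 113 and 114 CPM.

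Of 14643 genes tested, 9571 (65.4%) changed, 4712 higher and 4859 lower in ZIP (edgeR quasi-likelihood test, Benjamini-Hochberg). With library totals in place of scaling factors 4026 were higher and 5492 lower. At least 2-fold changes were fewer and lopsided: 458 genes were higher and 1610 lower, and at 4-fold 56 were higher and 652 lower. The replicates were close, with a biological coefficient of variation of 0.0245. Nothing in the labels says that they came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Of the 2068 genes changed at least 2-fold, 1609 (77.8%) had the untransduced level nearer to ZIP and 459 nearer to SCR. Among the genes lower in ZIP these numbers were 1366 and 244, and among those higher 243 and 215.

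Of the 10 genes with the largest rises in ZIP, GABBR2, a subunit of the GABA-B receptor, rose by 4.26 ± 0.73 on the log2 scale, the microtubule protein MAP1A by 3.85 ± 0.42 and the neuronal deubiquitinase UCHL1 by 3.55 ± 0.28. The netrin receptor UNC5B rose by 3.53 ± 0.15, to 19.6 and 19.3 CPM from 1.77 and 1.60, with 20.4 CPM in the untransduced library. IGFBP2, which binds insulin-like growth factors, rose by 3.47 ± 0.15, EPHA8 by 3.41 ± 0.56, ALDH1A1 by 3.01 ± 0.59, SRPX by 2.89 ± 0.16 and ROPN1L by 2.65 ± 0.18. The gelatinase MMP2 rose 6.97-fold, to 113 and 114 CPM from 16.2 and 16.4, with 22.8 in the untransduced library.

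Most of the largest falls were to no count at all. SIGLEC1, a sialic acid receptor of macrophages, had 445 counts over the SCR libraries and none in ZIP, so it was at least 159-fold lower against a floor of 3 counts over the group. By the same floor the lymphocyte and myeloid activation marker CD69 was at least 134-fold lower, the decoy interleukin-1 receptor IL1R2 at least 109-fold, and the interferon-induced EPSTI1 at least 81.2-fold. IL24 was at least 28.3-fold lower, OCSTAMP, a protein of osteoclast fusion, at least 27.5-fold, the endothelial lipase LIPG at least 26.8-fold, MIR9-3HG at least 22.2-fold and the sperm calcium channel gene CATSPER1 at least 18.96-fold. All had adjusted p-values of 3.7e-07 or less (edgeR quasi-likelihood test, Benjamini-Hochberg). In the untransduced library SIGLEC1, EPSTI1 and LIPG stood at 0.0417 CPM, IL1R2 at 0.209, CD69 at 0.584 and CATSPER1 at 0.125, while IL24, OCSTAMP and MIR9-3HG had no count.

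The gene lists were fixed before the data were examined. In ZIP against SCR 18 of 31 lists with at least 5 measured genes passed camera with a preset correlation of 0.01, 5 upward and 13 downward. With a correlation estimated from the data 0 lists passed camera, the smallest adjusted p was 0.209, and 4 lists had an unadjusted p under 0.05. By fry, which asks whether the genes of a list move one way on balance, 27 lists passed. The counts of members that follow are over all genes tested. Adjusted over the list alone they were the same for every list in this comparison except cytosolic ribosomal proteins, where 56 rather than 55 fell, and the chromosome 5q list, where 12 rather than 11 fell.

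All 27 measured genes of the type I interferon response fell in ZIP, with a median log2 fold change of -2.46 (camera adjusted p = 1.8e-13, and adjusted p = 0.209 with an estimated correlation). IFI6 fell by 4.67 ± 0.16 and the antiviral GTPase MX1 by 4.66 ± 0.17 on the log2 scale, OAS3 by 2.83 ± 0.08 and XAF1 by 2.29 ± 0.07. IFI6 stood at 43.3 and 41.6 CPM in SCR, 1.37 and 2.03 in ZIP and 1.17 in the untransduced library. Of 15 NF-kB and inflammatory cytokine genes 12 fell and 2 rose (median -1.90, camera adjusted p = 1.1e-05, and adjusted p = 0.229 with an estimated correlation). The neutrophil chemokine CXCL8 fell to 152 and 152 CPM from 592 and 574, with 43.6 in the untransduced library, and the monocyte chemokine CCL2 to 2.74 and 2.77 from 64.5 and 64.7, with 10.0 in the untransduced library. TNF fell by 1.61 ± 0.05 and NFKB2 by 2.62 ± 0.09 on the log2 scale. Of 14 immediate early genes, which respond quickly to growth factors and stress, 12 fell and 2 rose (median -1.27, camera adjusted p = 5.2e-05, and adjusted p = 0.229 with an estimated correlation). JUN fell by 1.36 ± 0.03, FOS by 1.44 ± 0.03, ZFP36 by 1.90 ± 0.05 and JUNB by 1.13 ± 0.03. JUN stood at 7.47 CPM in the untransduced library, 250.4 and 250.3 in SCR, and 99.4 and 94.97 in ZIP.

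Markers of monocytes and macrophages fell in ZIP in 12 of 14 measured genes and rose in 1 (median -2.53, camera adjusted p = 8.2e-05, and adjusted p = 0.229 with an estimated correlation). CD14, the endotoxin co-receptor, fell to 3.50 and 4.18 CPM from 54.7 and 53.6, with 2.09 in the untransduced library. The colony-stimulating factor receptor CSF1R fell to 7.19 and 6.91 CPM from 41.1 and 44.0, with 1.29 in the untransduced library, and the proteoglycan VCAN to 0.163 and 0.0827 from 20.9 and 21.2. Of 16 neutrophil maturation genes 12 fell and 1 rose (median -1.02, camera adjusted p = 0.00012, and adjusted p = 0.301 with an estimated correlation), among them the integrin chains ITGB2 (-1.33 ± 0.02) and ITGAM (-2.04 ± 0.09). Of 8 NADPH oxidase genes 6 fell and 1 rose (median -0.44, camera adjusted p = 0.016, and adjusted p = 0.374 with an estimated correlation). The catalytic subunit CYBB fell by 0.91 ± 0.03 on the log2 scale. NCF1 fell by 1.79 ± 0.10, but it has near-identical pseudogenes and its counts are uncertain. Of 17 myeloid transcription factors 12 fell and 3 rose (median -0.43, camera adjusted p = 0.0035, and adjusted p = 0.229 with an estimated correlation). CEBPB fell by 1.78 ± 0.04, GATA2 by 1.17 ± 0.04 and IRF8 by 0.79 ± 0.04.

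Primary granule proteins, the proteases and peroxidase that promyelocytes store, rose in ZIP in 13 of 15 genes and fell in 1 (median 0.76, camera adjusted p = 3.8e-07, and adjusted p = 0.301 with an estimated correlation). Myeloperoxidase, MPO, rose to 17062 and 16596 CPM from 9974 and 9999, with 19034 in the untransduced library. PRTN3 rose by 1.97 ± 0.02, ELANE by 1.71 ± 0.03 and CTSG by 2.17 ± 0.03 on the log2 scale. ELANE stood at 1378 CPM in the untransduced library, 487 and 456 in SCR, and 1572 and 1504 in ZIP. Of 9 measured secondary and tertiary granule genes 2 rose and 4 fell, and the list did not pass (camera adjusted p = 0.388). Its gelatinase MMP9 fell by 4.03 ± 0.18 on the log2 scale and CEACAM8 rose by 1.87 ± 0.32.

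All 22 measured cholesterol biosynthesis genes fell in ZIP (median -1.77, camera adjusted p = 2.5e-17, and adjusted p = 0.209 with an estimated correlation). HMGCS1, which makes the precursor of mevalonate, fell by 3.00 ± 0.03 and INSIG1, the sterol-sensing regulator, by 2.55 ± 0.03 on the log2 scale. HMGCS1 stood at 729 and 714 CPM in SCR, 90.5 and 90.0 in ZIP and 192 in the untransduced library. All 13 mitochondrially encoded mRNAs rose (median 0.67, camera adjusted p = 5.0e-12, and adjusted p = 0.301 with an estimated correlation), and their share of all counts was 7.25% in the untransduced library, 3.64% and 3.76% in SCR, and 5.53% and 5.57% in ZIP. MT-CYB rose by 0.96 ± 0.02 and MT-CO1 by 0.40 ± 0.01. Of 27 MYC target and ribosome biogenesis genes 24 rose and 2 fell (median 0.39, camera adjusted p = 7.7e-10, and adjusted p = 0.229 with an estimated correlation). The polyamine enzyme ODC1 rose by 1.02 ± 0.02 and UTP20, a factor of small subunit processing, by 0.88 ± 0.03. Cytosolic ribosomal proteins moved the other way, with 55 of 76 lower and 8 higher (median -0.15, camera adjusted p = 6.1e-09, and adjusted p = 0.501 with an estimated correlation). RPS18 fell by 0.41 ± 0.02 and RPL37 by 0.50 ± 0.02. Many ribosomal protein genes have processed pseudogenes that can share reads.

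Of 31 G2/M and mitosis genes 22 fell and 3 rose (median -0.22, camera adjusted p = 0.00025, and adjusted p = 0.229 with an estimated correlation), with HMMR at -0.73 ± 0.03 and PTTG1 at -0.65 ± 0.03. Of 15 cell cycle inhibitors 10 fell and 2 rose (median -0.49, camera adjusted p = 0.0035, and adjusted p = 0.229 with an estimated correlation). CDKN1A, which encodes the p53-induced inhibitor p21, fell by 5.46 ± 0.21, to 0.882 and 0.703 CPM from 34.7 and 36.4, with 0.668 in the untransduced library. Of 27 apoptosis regulators 16 fell and 4 rose (median -0.24, camera adjusted p = 0.0036, and adjusted p = 0.229 with an estimated correlation). PMAIP1 and TNFRSF10B, both inducible by p53 and stress, fell by 1.33 ± 0.03 and 1.35 ± 0.04, and the survival factor MCL1 also fell, by 0.61 ± 0.03.

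Genes of the 5q region commonly deleted in MDS fell in 11 of 15 measured and rose in 2 (median -0.36, camera adjusted p = 0.00094, and adjusted p = 0.229 with an estimated correlation). TIFAB fell by 1.78 ± 0.08, CTNNA1 by 2.08 ± 0.11, NR3C1 by 0.70 ± 0.04 and EGR1 by 1.83 ± 0.10. Genes of chromosome 5 as a whole also stood lower in ZIP, with a median log2 fold change of -0.23 relative to all protein-coding genes. Of 12 heat shock genes 8 rose and 3 fell (camera upward, adjusted p = 0.015, and adjusted p = 0.323 with an estimated correlation). Their median was 0.28 and their mean -0.04: HSPB1 fell by 2.05 ± 0.06, HSP90AA1 rose by 0.68 ± 0.02 and HSPA8 rose by 0.52 ± 0.02. Of 14 microRNA biogenesis and effector genes 7 rose and 1 fell (median 0.12, camera adjusted p = 0.043, and adjusted p = 0.323 with an estimated correlation). DICER1 rose by 0.57 ± 0.03 and the Argonaute genes AGO1 and AGO2 by 0.65 ± 0.04 and 0.80 ± 0.05, while AGO4 fell by 0.89 ± 0.04. The call for this list was lost without SCR 1 (adjusted p = 0.0641), without SCR 2 (adjusted p = 0.0573), without ZIP 2 (adjusted p = 0.0510) and with library totals in place of scaling factors (adjusted p = 0.0683), all by camera.

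The other lists did not pass camera in ZIP against SCR. Some of them passed by fry, among them the reported miR-378a-3p targets, downward (fry adjusted p = 0.0094). The median log2 fold change of those targets was -0.00227. Of 18 reported miR-378a-3p targets 8 rose and 7 fell (camera adjusted p = 0.722): IGF1R rose by 0.68 ± 0.03 and GALNT7 by 0.58 ± 0.03, while the cytoskeletal gene VIM fell by 1.34 ± 0.03 and KSR1 by 0.91 ± 0.05. Of 10 stem and progenitor genes 2 rose and 5 fell, with KIT, the stem cell factor receptor, at 2.19 ± 0.11. Of 25 genes recurrently mutated in MDS 10 rose and 13 fell, with IDH1 at -1.16 ± 0.03 and U2AF1, which has a near-identical copy in GRCh38 and is uncertain, at 0.48 ± 0.03. Of 20 ATF4 and unfolded protein response genes 7 rose and 12 fell, with the chaperone CALR at 1.14 ± 0.01 and DDIT4 at -1.65 ± 0.05. Of 21 glycolysis genes 8 rose and 8 fell, with the glucose transporter SLC2A3 at -3.72 ± 0.08 and GPI at 0.64 ± 0.02. Of 18 fatty acid oxidation and PGC-1 network genes 9 rose and 7 fell (median 0.14, mean -0.03), with CPT1A, the carnitine transferase of fatty acid import, at 1.02 ± 0.03 and PPARD at -2.07 ± 0.09. Of 42 nuclear-encoded oxidative phosphorylation genes 19 rose and 15 fell, and of 29 DNA replication genes 8 rose and 12 fell (median 0.00, mean -0.06). With library totals, which moved the median of all genes to -0.06, the medians of these 2 lists, near 0, changed sign, as did that of the reported targets with DESeq2's size factors. The histone list had 6 of 11 genes lower, the megakaryocyte list 1 higher and 3 lower of 7, the T and NK cell list 1 higher and 2 lower of 5, and the reference gene list 8 higher and 5 lower of 15. Below 5 measured genes no list test was run: the erythroid list had 1 higher and 1 lower of 4, the B cell list 1 lower of 2, the epithelial and fibroblast list 1 lower of 3, and the myeloid microRNA host list MIR17HG higher (2.03 ± 0.21) and MIR155HG lower (-0.99 ± 0.20).

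The second comparison set the SCR cells beside the untransduced cells, which had no vector and no puromycin. In SCR all 27 interferon genes and 13 of 14 monocyte and macrophage markers were higher (camera adjusted p = 3.9e-12 and 1.2e-05, and adjusted p = 0.252 for each with an estimated correlation). Primary granule genes were lower in 14 of 15 (camera adjusted p = 3.2e-08, and adjusted p = 0.280 with an estimated correlation). JUN rose from 7.47 CPM to 250.4 and 250.3, and CSF1R rose from 1.29 to 41.1 and 44.0. MPO fell from 19034 CPM to 9974 and 9999. This comparison rests on 1 untransduced library, which is assumed to vary like the others, and its difference from SCR has no replicate check on that side.

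Of 15832 genes tested, 10273 changed, 5178 higher and 5095 lower in SCR (edgeR quasi-likelihood test, Benjamini-Hochberg). At least 2-fold, 2302 were higher and 927 lower, and at 4-fold 1298 were higher and 191 lower. With library totals in place of scaling factors 6157 were higher and 4121 lower, and the median log2 fold change of all genes moved from 0.02 to 0.13.

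The largest rises were from no count in the untransduced library, so they are bounds against a floor of 3 counts over the group. The interferon-induced gene OASL was at least 59.1-fold higher in SCR, the serotonin receptor HTR7 at least 56.9-fold, the potassium channel KCNA3 at least 40.0-fold and the activin subunit INHBA at least 39.7-fold. CAMK2D was at least 38.5-fold higher, BMP2 at least 30.0-fold, the transcription factor HAND2 at least 29.7-fold, the cytokine receptor IL31RA at least 28.3-fold, IFI44L at least 27.7-fold and the transcription factor ONECUT2 at least 27.2-fold. Among the 10 largest falls, CEACAM8, an adhesion molecule of secondary granules, fell by 5.59 ± 0.28 on the log2 scale, from 23.8 CPM to 0.552 and 0.428, and the collagenase MMP8 by 3.88 ± 0.58. OLFM4 had 31 counts in the untransduced library and 1 over SCR, a ratio of 66.5 with a 95% counting interval of 11.01 to 2693. KCNK17 and NDN had 3 counts over SCR, with ratios of 50.3 (95% counting interval 16.6 to 250.4) and 25.6 (8.08 to 130). ART3 fell by 4.16 ± 0.52 and PPP1R1B by 3.79 ± 0.76. GRIN1 fell by 4.35 ± 0.42 and LRRC26 fell by 4.07 ± 0.22. These 2 genes overlap on opposite strands of chromosome 9 (GRCh38, 137138390 to 137168762 and 137168758 to 137170051), and whether counting used strand is not given in the sources used here.

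Of 32 lists with at least 5 measured genes 15 passed camera in SCR against untransduced, 10 upward and 5 downward, and 0 passed with an estimated correlation (smallest adjusted p = 0.252, with 5 lists under 0.05 before adjustment). By fry 27 passed. Adjusted over the list alone the counts of called members were the same, except that 7 rather than 6 secondary and tertiary granule genes and 31 rather than 30 oxidative phosphorylation genes fell. All 27 interferon genes rose (median 4.03, camera adjusted p = 3.9e-12, and adjusted p = 0.252 with an estimated correlation), with XAF1 at 6.37 ± 0.37, IFI6 at 5.18 ± 0.28 and BST2, which tethers virus particles, at 2.70 ± 0.09. Of 14 monocyte and macrophage markers 13 rose (median 3.01, camera adjusted p = 1.2e-05, and adjusted p = 0.252 with an estimated correlation), with CSF1R at 5.03 ± 0.25, CD14 at 4.69 ± 0.20 and the chemokine receptor CCR2 at 2.72 ± 0.13. Of 15 NF-kB and cytokine genes 14 rose (median 1.92, camera adjusted p = 1.4e-07, and adjusted p = 0.280 with an estimated correlation), with CXCL8 at 3.74 ± 0.04 and TNF at 2.98 ± 0.09. Of 14 immediate early genes 13 rose (median 3.15, camera adjusted p = 7.5e-06, and adjusted p = 0.252 with an estimated correlation), with FOS at 4.57 ± 0.11, while the remaining member, MYC, fell by 1.13 ± 0.02.

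Cholesterol biosynthesis genes rose in 21 of 22 (median 0.84, camera adjusted p = 2.5e-12, and adjusted p = 0.252 with an estimated correlation), with HMGCS1 at 1.91 ± 0.03. Of 31 G2/M and mitosis genes 23 rose and 4 fell (median 0.42, camera adjusted p = 2.8e-06, and adjusted p = 0.252 with an estimated correlation), with the proliferation marker MKI67 at 1.52 ± 0.03 and CENPF at 1.26 ± 0.04. Of 15 cell cycle inhibitors 11 rose and 2 fell (median 0.80, camera adjusted p = 0.0029, and adjusted p = 0.280 with an estimated correlation), with CDKN1A at 5.72 ± 0.35. Of 28 apoptosis regulators 14 rose and 5 fell (median 0.22, camera adjusted p = 0.015, and adjusted p = 0.280 with an estimated correlation), with PMAIP1 at 2.39 ± 0.05. Of 15 genes of the 5q list 11 rose and 4 fell (median 0.60, camera adjusted p = 0.0079, and adjusted p = 0.280 with an estimated correlation). CTNNA1 rose by 6.20 ± 0.59 and DIAPH1 by 0.88 ± 0.03, while RPS14 fell by 0.55 ± 0.02, and chromosome 5 as a whole had a median of 0.35 relative to all protein-coding genes. Of 25 genes recurrently mutated in MDS 19 rose and 3 fell (median 0.34, camera adjusted p = 0.00020, and adjusted p = 0.280 with an estimated correlation), with IDH1 at 1.56 ± 0.04, CBL at 1.44 ± 0.04 and SF3B1 at 0.57 ± 0.03.

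In SCR 5 lists passed downward. Primary granule genes fell in 14 of 15 (median -1.25, camera adjusted p = 3.2e-08, and adjusted p = 0.280 with an estimated correlation), with PRTN3 at -1.95 ± 0.02 and ELANE at -1.55 ± 0.03, while lysozyme, LYZ, which monocytes also make, rose by 1.79 ± 0.02. All 13 mitochondrially encoded mRNAs fell (median -1.02, camera adjusted p = 1.8e-14, and adjusted p = 0.285 with an estimated correlation), with MT-CO3 at -1.27 ± 0.01. Of 42 nuclear-encoded oxidative phosphorylation genes 30 fell and 5 rose (median -0.27, camera adjusted p = 4.1e-05, and adjusted p = 0.442 with an estimated correlation), with ATP5MC1 at -1.09 ± 0.04. Cytosolic ribosomal proteins fell in 75 of 76 (median -0.58, camera adjusted p = 1.1e-35, and adjusted p = 0.280 with an estimated correlation), with RPLP2 at -0.93 ± 0.02. Of 27 MYC target and ribosome biogenesis genes 19 fell and 7 rose (median -0.34, camera adjusted p = 0.00051, and adjusted p = 0.346 with an estimated correlation), with FBL, the nucleolar methyltransferase, at -1.03 ± 0.03.

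Among lists that did not pass, IRF8, a transcription factor of monocyte precursors, rose by 5.14 ± 0.16 in SCR and the granulocyte factor CEBPE fell by 1.31 ± 0.03, in a list of 18 myeloid transcription factors with 13 higher and 4 lower. That list passed with library totals in place of scaling factors (camera adjusted p = 0.0383). The reference gene list had 5 higher and 9 lower of 15 and passed downward without SCR 1 (camera adjusted p = 0.0431) or without ZIP 2 (camera adjusted p = 0.00815). The histone list, with 8 of 13 higher and a median of 1.51 (1.44 with genes without a count at their bound), passed without ZIP 1 (camera adjusted p = 0.0479), and the neutrophil maturation list, with 8 higher and 6 lower of 17, passed without ZIP 2 (camera adjusted p = 0.0386). Mean and median differed in sign for the heat shock list (median -0.10, mean 0.44), the megakaryocyte list (-0.25 and 0.75), the fatty acid oxidation list (-0.02 and 0.21) and the erythroid list (0.08 and -0.30), and with library totals, which raised all genes alike, the heat shock and fatty acid oxidation medians turned positive.

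**Figure D2:**
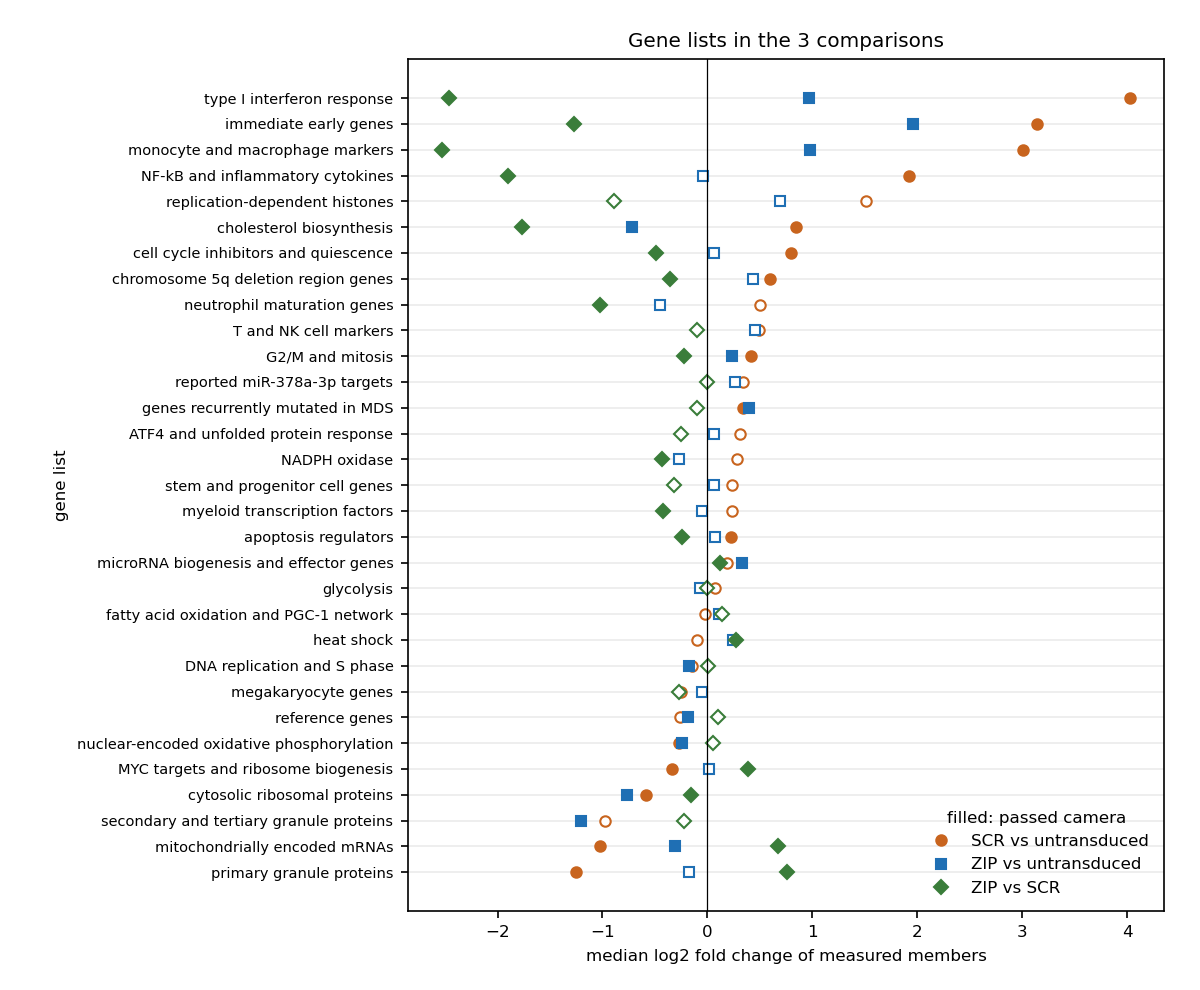
Median log2 fold change of the measured members (horizontal axis) of each list with at least 5 measured genes in every comparison (vertical axis), for SCR against untransduced (circles), ZIP against untransduced (squares) and ZIP against SCR (diamonds). Filled points passed camera with a preset correlation of 0.01, and the interferon list lay at 4.03, 0.97 and -2.46 in these comparisons, and cholesterol biosynthesis at 0.84, -0.72 and -1.77.

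The third comparison set the ZIP cells beside the untransduced cells. In ZIP 75 of 76 cytosolic ribosomal protein genes and 21 of 22 cholesterol biosynthesis genes were lower (camera adjusted p = 3.8e-51 and 2.2e-11, and adjusted p = 0.492 for each with an estimated correlation). MPO stood at 17062 and 16596 CPM in ZIP and 19034 in untransduced cells. IRF8 rose by 4.35 ± 0.16 on the log2 scale, from 2.84 CPM to 59.2 and 56.9. The eosinophil and basophil protein CLC fell by 3.82 ± 0.07, from 118 CPM to 8.66 and 8.02. The single untransduced library limits this comparison as it does the second.

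Of 15832 genes tested, 9212 changed, 4507 higher and 4705 lower in ZIP (edgeR quasi-likelihood test, Benjamini-Hochberg). At least 2-fold, 1377 were higher and 822 lower, and at 4-fold 605 and 186. With library totals 5018 of all changed genes were higher and 4208 lower, so which direction held more genes depended on the scaling. The largest rises were again from no count in the untransduced library, with PLXDC2 at least 20.8-fold higher, KCNA3 at least 17.3-fold, HAND2 at least 16.8-fold, ONECUT2 at least 14.7-fold, CAMK2D at least 13.4-fold and HTR7 at least 10.2-fold. With 1 count in the untransduced library, UCHL1 had a ratio of 191 (95% counting interval 34.6 to 7669), EPB41L2 of 158 (28.2 to 6252), SLC41A1 of 99.0 (17.5 to 3903) and TLE1 of 94.1 (16.9 to 3782). Among the 10 largest falls, MMP8 fell by 4.63 ± 0.70, lactoferrin, LTF, fell by 3.995 ± 0.30, the erythroid and eosinophil factor GATA1 fell by 4.10 ± 0.56, the histamine enzyme HDC fell by 3.90 ± 0.55 and the mast cell protease CPA3 fell by 3.75 ± 0.27. KCNK17 fell by 4.48 ± 0.62, PPP1R1B fell by 4.20 ± 0.84 and RAMP1 fell by 3.83 ± 0.38, and GCSAML had 3 counts over ZIP, a ratio of 23.5 (95% counting interval 7.11 to 117).

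In ZIP against untransduced 13 of 32 lists passed camera, 6 upward and 7 downward, and 0 passed with an estimated correlation (smallest adjusted p = 0.492, with 1 list under 0.05 before adjustment). By fry 26 passed. This list test was added after the data were seen. Of 27 interferon genes 17 rose and 1 fell (median 0.97, camera adjusted p = 0.0051, and adjusted p = 0.492 with an estimated correlation), with XAF1 at 4.09 ± 0.38. Of 14 monocyte markers 9 rose (median 0.98, camera adjusted p = 0.030, and adjusted p = 0.492 with an estimated correlation), with CCR2 at 2.45 ± 0.13 and CSF1R at 2.44 ± 0.26. Of 14 immediate early genes 9 rose and 3 fell (median 1.96, camera adjusted p = 0.039, and adjusted p = 0.492 with an estimated correlation), with JUN at 3.70 ± 0.09. Without ZIP 2 these 3 lists did not pass (camera adjusted p = 0.0602 for each). With library totals in place of scaling factors the monocyte and immediate early lists did not pass (camera adjusted p = 0.0526 and 0.0544). Of 31 G2/M genes 18 rose and 7 fell (median 0.24, camera adjusted p = 0.0051, and adjusted p = 0.492 with an estimated correlation), of 25 genes recurrently mutated in MDS 19 rose and 4 fell (median 0.40, camera adjusted p = 3.9e-05, and adjusted p = 0.492 with an estimated correlation), and of 15 microRNA biogenesis genes 10 rose and 3 fell (median 0.33, camera adjusted p = 0.019, and adjusted p = 0.501 with an estimated correlation), with AGO2 at 1.76 ± 0.08.

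Downward, cytosolic ribosomal proteins fell in 75 of 76 (median -0.76, camera adjusted p = 3.8e-51, and adjusted p = 0.492 with an estimated correlation), with RPL34 at -1.22 ± 0.03. Cholesterol biosynthesis genes fell in 21 of 22 (median -0.72, camera adjusted p = 2.2e-11, and adjusted p = 0.492 with an estimated correlation), with MSMO1 at -1.66 ± 0.05. Mitochondrially encoded mRNAs fell in 11 of 13 and rose in 1 (median -0.31, camera adjusted p = 2.0e-07, and adjusted p = 0.501 with an estimated correlation), and nuclear-encoded oxidative phosphorylation genes fell in 31 of 42 and rose in 2 (median -0.24, camera adjusted p = 1.1e-06, and adjusted p = 0.501 with an estimated correlation). Of 29 DNA replication genes 18 fell and 6 rose (median -0.18, camera adjusted p = 0.0081, and adjusted p = 0.504 with an estimated correlation). Secondary and tertiary granule genes fell in 7 of 11 and rose in 1 (median -1.20, camera adjusted p = 0.038, and adjusted p = 0.492 with an estimated correlation), a call lost without ZIP 1 (camera adjusted p = 0.0635) or without ZIP 2 (camera adjusted p = 0.0705). The reference genes fell in 10 of 15 and rose in 4 (median -0.18, camera adjusted p = 0.039, and adjusted p = 0.504 with an estimated correlation), a call lost with library totals (camera adjusted p = 0.0654). Primary granule genes did not pass, with 6 of 15 higher and 8 lower, where CTSG rose by 0.75 ± 0.03 and AZU1 fell by 0.74 ± 0.03. Median and mean, or median and test, differed in sign for the megakaryocyte (median -0.05, mean 0.24), T and NK cell (0.46 and -0.03), NF-kB (-0.05 and 0.24, test upward), myeloid transcription factor (-0.05 and 0.29) and stem cell (0.07 and 0.12, test downward) lists, none of which passed, and with library totals, which moved the median of all genes to 0.05, the megakaryocyte, NF-kB and myeloid transcription factor medians turned positive. Heat shock genes, 7 of 12 higher and 3 lower, passed upward without ZIP 2 (camera adjusted p = 0.0483). Adjusted over the list alone 33 rather than 31 oxidative phosphorylation genes and 5 rather than 4 genes recurrently mutated in MDS fell, and no other list that passed changed its counts.

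The calls of SCR and ZIP against the same untransduced library overlapped. Among the 15832 genes, 3071 were higher in both and 3300 lower in both, where independent lists of those sizes would share 1474 and 1514 and 20 simulations of unchanged groups against that library shared at most 3 and 2. Neither number holds both the shared library and real changes, so the excess over them is not a measure of a shared change. The correlation of log2 fold changes across genes, which are not independent replicates, was 0.69, and unchanged groups simulated against the same library gave 0.68, so it does not tell a shared change from the shared library. The covariance was 0.864 against a simulated 0.0699, with 0.0748 the highest of 20 simulations. The untransduced library is single and could not be divided, so part of the overlap may come from the shared control.

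Genes that differed between ZIP and SCR were unevenly spread over chromosomes. This test was chosen after the data were seen. Over 12122 protein-coding genes, with log2 fold changes centred on their median, the median in ZIP against SCR was -0.19 ± 0.02 (SE) on chromosome 1 (1241 genes), -0.13 ± 0.02 on chromosome 2 (811), -0.23 ± 0.02 on chromosome 5 (532) and -0.21 ± 0.02 on chromosome 6 (633). Each had p = 1e-04, the smallest that 10000 permutations of genes over chromosomes can give (Benjamini-Hochberg adjusted p = 0.000256). Genes are not replicates here: the permutations treat neighbouring genes as independent, and variation between cultures does not enter the p-values of this test. The other 19 chromosomes had medians from -0.00288 to 0.12, and 12 of them passed upward, partly by the arithmetic of centring. In SCR against untransduced, over 12536 genes, chromosomes 1, 2, 5 and 6 stood higher, at 0.19, 0.17, 0.35 and 0.24, and the others ranged from -0.27 on chromosome 19 to 0.04. Of these others 10 passed downward (Benjamini-Hochberg adjusted permutation test), partly by the same arithmetic, so shifts in this comparison were not limited to those 4 chromosomes. In ZIP against untransduced they stood at 0.05, 0.07, 0.15 and 0.03, and the others ranged from -0.19 to 0.12. There 11 of 23 chromosomes passed, 5 of them downward. Chromosomes 1, 2 and 5 passed upward (Benjamini-Hochberg adjusted permutation p = 0.0106, 0.0023 and 0.00115) and chromosome 6 did not pass (0.227).

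**Figure D3:**
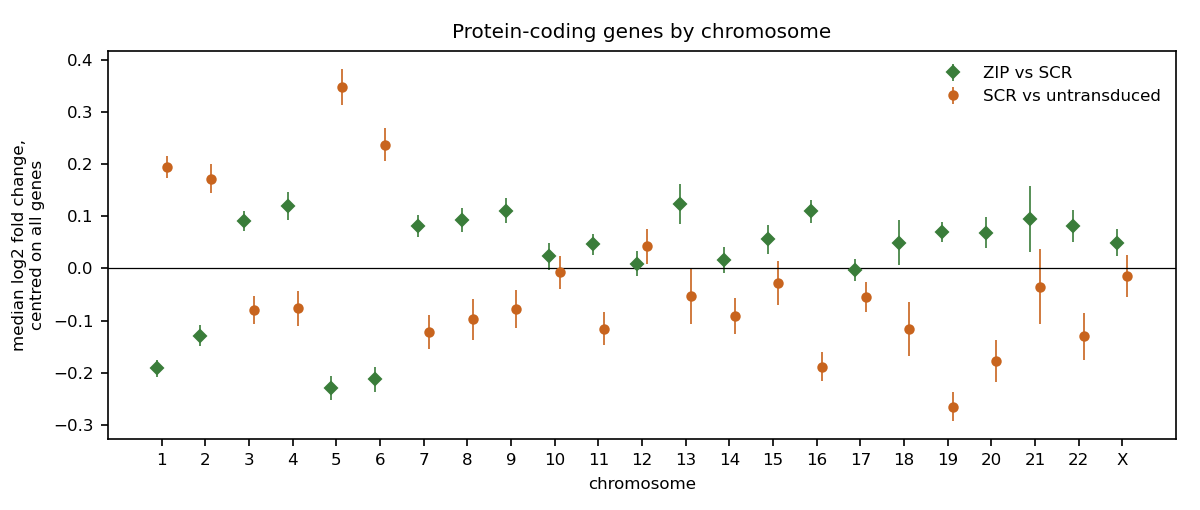
Median log2 fold change of protein-coding genes (vertical axis), centred on all protein-coding genes, for each chromosome (horizontal axis), in ZIP against SCR (diamonds) and SCR against untransduced (circles), with bars of 1 standard error of the median. Chromosomes 1, 2, 5 and 6 lay at -0.13 or below in ZIP against SCR and at 0.17 or above in SCR against untransduced.

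The 3' UTR sites of miR-378a-3p were tested to ask whether genes that carry the seed match AGTCCAG moved together. The mean log2 fold change in ZIP against SCR was -0.23 over 1589 genes with a site and -0.20 over 10485 without, a difference of -0.03 (permutation test over genes, p = 0.293). Genes are not replicates in this test. With a background matched on 3' UTR length and expression the difference was -0.06 (permutation test, p = 0.018), which was at percentile 15 among 200 control words of the same bases.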

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

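Tests of scaling, of mixed cells and of the chromosome medians were chosen after the results were seen, and those of exchanged labels, of gene stretches and of target sites before.

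Genes that moved in opposite directions in SCR and ZIP, each against the untransduced library, were listed where the difference also passed the ZIP against SCR test (edgeR quasi-likelihood test). There were 473 genes higher in SCR and lower in ZIP, and 469 genes lower in SCR and higher in ZIP. The cholesterol biosynthesis list was the 1 list of this kind, with a median log2 fold change of -1.77 in ZIP against SCR. With an estimated correlation its camera calls were lost (adjusted p = 0.209 in ZIP against SCR, 0.252 in SCR against untransduced and 0.492 in ZIP against untransduced). Its members HMGCS1 (-3.00), INSIG1 (-2.55), MSMO1 (-2.09) and LSS (-1.88) went the same way.

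Of the named genes, 25 were called higher in SCR and lower in ZIP than in untransduced cells. CD69 was at least 134-fold lower in ZIP than in SCR, IL1R2 at least 109-fold and CATSPER1 at least 18.96-fold. The log2 fold change was -8.05 for FADS2, -4.55 for CCL2, -3.64 for the aldolase ALDOC, -1.90 for ZFP36 and -1.79 for NCF1, whose pseudogenes make it uncertain. It was -1.78 for CEBPB, -1.65 for the stress gene DDIT4, -1.52 for EPOR, -1.20 for the apoptosis gene BMF, -1.17 for GATA2, -1.13 for JUNB and -1.05 for TRIB3. It was -0.97 for BTG1 and for the cell cycle inhibitor CDKN1B, -0.91 for KSR1, -0.61 for RAP1A, -0.49 for NUSAP1 and -0.27 for FLI1. In the untransduced library CATSPER1 stood at 0.125 CPM, which equals the floor of 3 counts there, and IL1R2 at 0.209 CPM. The fall of CATSPER1 from untransduced to ZIP is therefore not resolved, and that of IL1R2 rests on few counts of 1 library. Some other falls in ZIP against untransduced were small, at -0.15 for FLI1 and -0.18 for BTG1, NUSAP1 and ZFP36.

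The other 16 were lower in SCR and higher in ZIP than in untransduced cells. They were GABBR2 (4.26 in ZIP against SCR), MAP1A (3.85), IGFBP2 (3.47), MMP2 (2.80), CTSG (2.17), ELANE (1.71), CPT1A (1.02), ODC1 (1.02), IGF1R (0.68), HSP90AA1 (0.68), the chaperones PDIA4 (0.65) and HSPH1 (0.61), GALNT7 (0.58), DICER1 (0.57), the nucleolar gene NOLC1 (0.57) and U2AF1 (0.48). Some rises in ZIP against untransduced were small, at 0.13 for IGF1R, 0.16 for ELANE, 0.21 for U2AF1 and 0.24 for ODC1. Some falls in SCR against untransduced were small, at -0.09 for HSP90AA1, -0.14 for GALNT7, -0.15 for PDIA4 and -0.19 for DICER1. They rest on 1 untransduced library and on the scaling, since library totals moved the median of all genes there from 0.02 to 0.13. With DESeq2 the calls against untransduced were lost for EPOR in ZIP (adjusted p = 0.120, DESeq2 Wald test) and for FLI1 in SCR (0.152) and ZIP (0.0804). Without ZIP 1 the call of EPOR in ZIP against untransduced was lost too (log2 fold change -0.50, adjusted p = 0.0652, edgeR quasi-likelihood test).

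The SCR libraries stood farther from the untransduced library than the ZIP libraries did: 3229 against 2199 genes changed at least 2-fold. Scaling as the whole cause is argued against, since the lowest ratio of these counts under TMM, RLE factors and library totals was 1.47. As the whole cause, dilution by cells that make none of PRTN3, ELANE, CTSG, AZU1, MPO and MS4A3 is argued against too. These genes would then fall by 1 factor. Their log2 fold changes instead ran from -1.95 to -0.37, a span of 1.58 with an SE of 0.0391. Dilution by cells that make some of them, or dilution together with regulation, could give unequal falls and was not tested. Exchanged SCR and ZIP labels cannot be told apart from correct ones. The target sites, at percentile 15 of control words, decided neither way. MIR378A had too few counts, and counts at its locus need not measure the mature microRNA. A response of the cells to the SCR vector, and a difference in culture state, go with the groups in this design and stay open, untested.

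Genes on chromosomes 1, 2, 5 and 6 stood lower in ZIP than in SCR, and a bias of GC content, transcript length or expression as the whole cause is argued against, since the medians adjusted for these were -0.248 to -0.160, below the lowest of the other chromosomes (0.00035). A copy number difference between the cultures is a candidate explanation: split at the middle gene, all 8 parts of these chromosomes had medians of -0.104 or below, under the lowest part of the others (-0.0665), though the chromosomes had been picked for this shift. The parts did not separate in SCR against untransduced (0.128 or above, others up to 0.150) or in ZIP against untransduced (-0.0362 to 0.199, others -0.226 to 0.189). Within chromosomes, the largest running median was -0.614 (0.614 in size, against 0.564 for the highest of 1000 random gene orders) on chromosome 1, and on no other chromosome was that bound passed, so this test leaves copy number of stretches open. Regulation of genes that happen to lie on these chromosomes was not tested and may also be the cause.

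Genes with a miR-378a-3p site were examined for release by the antisense vector, which would raise them in ZIP. The matched difference was -0.0581, in the other direction and below the median of control words (-0.0124), the bound set beforehand against release. It lay within their 5th to 95th percentiles (-0.103 to 0.0673), so it passed that bound by less than their spread, and release and its absence cannot be told apart at this size. The unmatched difference was -0.0266.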

How the results depend on the processing

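The alternatives with library totals, the untransduced library in place of SCR and every alternative of the ZIP against untransduced lists were chosen after the data were seen. Apart from the untransduced library in place of SCR, no called named gene or list changed direction: of 4871 results for named genes under an alternative 4835 kept their side of the threshold, 29 lost and 7 gained the call, and of 822 for lists 723 kept it, 59 lost and 40 gained it. Leaving out 1 library gave 8707 to 9088 changed genes in ZIP against SCR, 9548 to 10556 in SCR against untransduced and 8390 to 9169 in ZIP against untransduced, with 17 to 18, 15 to 17 and 10 to 13 lists passing. Where this leaves 1 library in a group, it is assumed to vary like the others.

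With a filter at a mean of 50 counts, which tests fewer genes (11361 in ZIP against SCR and 11307 in the others), 1152 genes changed at least 2-fold in ZIP against SCR (215 higher, 937 lower), 1759 in SCR against untransduced (1329 and 430) and 1114 in ZIP against untransduced (796 and 318). With DESeq2, 302 genes were at least 2-fold higher in ZIP than SCR and 565 at least 2-fold lower in SCR than untransduced. In ZIP against untransduced DESeq2 called 5956 genes, 2851 lower, and 1325 at least 2-fold, 908 higher and 417 lower; the cause was not tested. With protein-coding genes only, 12135 rather than 14643 genes were tested in ZIP against SCR. Then 287 rather than 458 were at least 2-fold higher in ZIP, and 1427 rather than 1610 at least 2-fold lower. The higher genes lost a larger share than the lower genes or the genes tested. With the untransduced library in place of SCR, 1377 were at least 2-fold higher and 822 lower, and of 6452 genes called both ways 2683 were called in the opposite direction.

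With an estimated correlation 0 lists passed camera in each comparison, and fry, which does not compare a list with other genes, passed 27 in SCR against untransduced and 26 in ZIP against untransduced. The difference at target sites passed when matched on 3' UTR length and expression (-0.0581, permutation test over genes, p = 0.0183), with the range over all alternatives running from there to 0.0320 for 8-base sites alone, which did not pass (permutation test, p = 0.504); the cause was not tested. Protein-coding genes held 97.2% of counts without the 10 most abundant genes.

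Deviations of same-numbered SCR and ZIP libraries correlated at 0.016 over 14643 genes. Over the 8761 genes with a mean of 10 CPM or more they correlated at 0.081. Both values are low, so the numbers were not taken to pair the libraries. A replicate block gave 9709 changed genes in place of 9571 and the microRNA biogenesis list was then not called (camera adjusted p = 0.122). No paired analysis was possible because there is 1 untransduced library, for either comparison with it. Genes near the floor of 3 counts are limited by depth.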
